A study of Schizosaccharomyces pombe with 8 samples.

How the data were processed

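Small RNA of 8 Schizosaccharomyces pombe strains was sequenced, 1 library per strain. Per the labels' protocols, RNA was taken from cultures in rich medium at 30 °C at an OD600 of 0.5 with hot phenol, RNA of 18 to 28 nt was purified from gels starting from 25 µg of small RNA, and libraries were made with a small RNA kit. The submitters' processing notes name CASAVA 1.8 and Bowtie 0.9.9.1. The genome build, the annotation and the counting rules are not given in the sources used here.

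The authors deposited 1 table of log2 values for 17962 elements, which are transcripts, UTRs, introns, non-coding RNAs, structural RNAs and repeats that partly overlap. Every library had its lowest value at exactly 3, which is log2 of 8, and the same linear total of 907489 after removal of 8. The values are therefore log2(n + 8), where n behaves as a read number divided by element length and scaled to a common total. Levels near the floor understate fold changes. The value of 1 read was found for each library by least squares on low multiples. With it between 79.5% and 89.2% of the elements above 0 came out as whole read numbers within 0.05, and the remainder hold fractions, as reads with several sites weighted by their number would give. Read numbers in the text are these recovered numbers, rounded. They come from calculation, and no count model was used. A common total means that a library with much rRNA has lower levels elsewhere.

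The largest element ends in the table equal the lengths of the 3 chromosomes in the reference used here (5579133, 4539804 and 2452883), and coordinates are given as in the table. The 142 tRNA and 47 rRNA elements found in the reference by name have its coordinates, but only 4.84% of protein-coding transcripts have the same start and end. Of 6898 gene elements 6729 were found in the reference table, which gave the symbols. The strand of counting was checked on structural RNA genes. Other elements that overlap a tRNA gene by at least 40 nt on the opposite strand had a median of 7777 wild-type reads (7 elements), against 50.8 for those on the same strand (6 elements) and 5.79 for the 170 tRNA elements themselves. For rRNA genes the medians were 151799 (3 elements), 27.2 (10) and 2.43 (52), and for snoRNA genes 195 (23), 27.0 (31) and 4.50 (54). The 3 elements opposite rRNA genes include the hsp3102 transcript and its 5′ UTR, which share nearly all their reads, so they are not 3 separate places. Abundant structural RNA was thus counted at elements on the opposite strand, and levels at a gene are read here as mostly antisense, which was not tested at protein-coding genes. Elements opposite a structural RNA gene hold its fragments.

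Because each strain has 1 library, no test across replicates was possible and no p-value is given. Differences are mutant minus wild type on the deposited log2 scale. An element entered a comparison if its level was at least 5, which is 2 above the floor, in the higher of the libraries compared, and was counted as changed at a difference of at least 1. Level ratios were computed from recovered reads and the value of a read, with 95% Clopper-Pearson intervals conditional on the sum of reads. PCR reads without molecular identifiers are not independent molecules, so intervals cover counting error only. Fractional reads were rounded for them. For a list of at least 3 elements past the filter, the median was placed among 10000 random lists matched on mean level. Members of random lists were drawn separately, so percentiles of lists whose members share reads are descriptive only. Elements past 1 in all 7 mutants were set beside 100 Poisson simulations with no difference except depth, because the mutants share 1 wild-type library.

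Lists, thresholds and the rule for named genes were fixed before the data were examined, with members matched by identifier, name or class. The plan named tlh1, tlh2, the SPAC212 and SPBCPT2R1 genes, mat2 and mat3. It held no separate list of pericentromeric non-coding RNAs and no list of telomeric, subtelomeric or pre-rRNA elements. Those lists were built from classes of the deposited table. The planned list of mating-type and subtelomeric heterochromatin, which also named cenH, was split, and cenH was not used. The planned transposon list was split into Tf2 and LTR elements. The lists held the ade6 locus (ade6, bub1, vtc4), nmt1, pericentromeric repeats and non-coding RNAs, telomeric and subtelomeric elements, SPAC212 and SPBCPT2R1 genes, mat2 and mat3 genes, Tf2, LTR and wtf elements, rRNA, pre-rRNA, tRNA, snRNA and snoRNA, mitochondrial elements, Paf1 complex, RNAi and heterochromatin, meiotic, housekeeping and ribosomal protein genes, non-coding RNA genes and protein-coding genes. Named were all members at the ade6 locus, nmt1 and the Paf1 complex, up to 4 members of highest mean level in other lists, up to 10 elements per direction in all mutants, and 3 genes per direction in each mutant. For Paf1 complex genes, reads in UTRs were subtracted from those of the transcript, because UTRs can overlap neighbours and can lie outside a deletion. The residues named in the labels were looked up in proteins translated from the reference.

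Because the filter can admit a member through the mutant alone, list medians under the planned setting without the filter were placed beside the others, which was decided after seeing the data. Medians over the mutants were set against 95% counting intervals from 200 Poisson draws of the reads. Alternatives were recentring on the median difference, quantile normalization, no level filter, a filter of 4 above the floor, a pseudocount of 4, thresholds of 1.5-fold and 4-fold, each mutant left out or used as the reference, means in place of medians, and lists without members that share reads. Alternatives added after seeing the data were rescaling linear levels by the median ratio over elements with at least 30 reads, and leaving out libraries that stood apart or were at odds with their labels. Scripts were tested on simulated data with 200 changed elements of 17962 per comparison, all past the filter and with at least 50 expected reads in wild type, so recovery at elements with fewer reads was not tested. Over the 7 comparisons with wild type, 94.9% to 100.0% of 4-fold changes and 19.8% to 30.8% of 2-fold changes passed the threshold of 1, at which a 2-fold change lies before the pseudocount lowers it. Intervals covered the simulated ratio in 93.0% to 98.0% of elements. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and BLAST 2.17.0.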

Results

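The series measured small RNAs of 18 to 28 nt in 8 strains of the fission yeast Schizosaccharomyces pombe grown at 30 °C to an OD600 of 0.5. It held 1 library per strain: wild type, deletions of Paf1 and of Leo1, and 5 strains labelled with the point alleles Paf1-G104R, Cdc73-G313R, Rot1-Q472Stop, Leo1-W157Stop and Paf1-Q264Stop. Paf1, Leo1 and Cdc73 are subunits of the Paf1 complex, which travels with RNA polymerase II during transcription. As far as the study is known, it asked how mutants of this complex change small RNA made against the ade6 gene, whose loss gives red colonies. The labels used here do not say whether the strains carry a construct with parts of ade6 or other genes, so reads given at ade6, nmt1 or the cox4 intron are placed by sequence and their source is not known. The deposited table gave a log2 level for 17962 genomic elements in each library. Summed over all elements, which overlap in part, the recovered reads numbered 6422460 in wild type, 1192682 in the library labelled Paf1 deletion, 2351402 in Leo1 deletion, 3139592 in Paf1-G104R, 917858 in Cdc73-G313R, 1868579 in Rot1-Q472Stop, 1386936 in Leo1-W157Stop and 3156301 in Paf1-Q264Stop. With 1 library per strain no difference below has a replicate check. Intervals are 95% exact binomial intervals that cover counting error only. Structural RNA was counted at elements on the opposite strand, as described under processing. Levels at a gene are therefore read as mostly antisense to it, which was not tested at protein-coding genes.

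The genes named in the strain labels were examined first. Over the leo1 transcript without its UTRs (chromosome 2, 3052520 to 3055287), the library labelled Leo1 deletion held 2 reads where the wild-type level predicted 29, a level ratio of 0.0691 (0.0082 to 0.260). A low value was not particular to the deletion, since leo1 was also below wild type in Cdc73-G313R at 0.239 (0.0630 to 0.642), Paf1-Q264Stop at 0.273 (0.130 to 0.523), Rot1-Q472Stop at 0.416 (0.190 to 0.817) and Paf1-G104R at 0.501 (0.283 to 0.848). Ratios here are not corrected for the general level of a library. In Cdc73-G313R the median log2 difference of all elements past the filter was -2.002, so its low leo1 value is not particular to leo1. The library labelled Paf1 deletion held 0 reads over paf1 where 1.47 were predicted, so a loss was not detectable at this depth. In each library of a point allele, 1 Paf1 complex gene had a level ratio to wild type whose interval lay above 1. In the library labelled Paf1 deletion this held for cdc73, with 9 reads and a ratio of 5.37 (1.84 to 16.0), and prf1, with 4 reads and a ratio of 19.1 (1.89 to 941). The library labelled Leo1-W157Stop had 519 reads over leo1, 30.4 times the wild-type level (23.3 to 40.3), and that labelled Paf1-Q264Stop had 181 reads over paf1 (chromosome 1, 1708728 to 1710347), 39.8 times (18.9 to 100). These genes matched the labels. In 3 libraries the raised gene was not the labelled one. The library labelled Paf1-G104R held 823 reads over prf1 (chromosome 2, 1255392 to 1257425), the Rtf1 homologue, against 1 read in wild type, a ratio of 1345 (241 to 53169), and 7 reads over paf1. That labelled Cdc73-G313R held 26 reads over paf1, 13.7 times wild type (5.81 to 37.5), and 0 over cdc73. That labelled Rot1-Q472Stop held 149 reads over cdc73 (chromosome 2, 2169820 to 2171436), 48.0 times (23.8 to 113), and 1 over prf1. The reference protein of prf1 has glutamine at the position that Rot1-Q472Stop names, while the gene with the symbol rot1 in the reference encodes 232 residues, too few to reach that position. The reference residues at the positions of the other 4 point alleles were those the labels name. Tpr1, a further gene of the list, had ratios between 0.224 and 1.74. Strain names below are therefore those of the library labels, and each direction given for the libraries labelled Paf1-G104R, Cdc73-G313R and Rot1-Q472Stop carries this conflict.

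**Figure D1:**
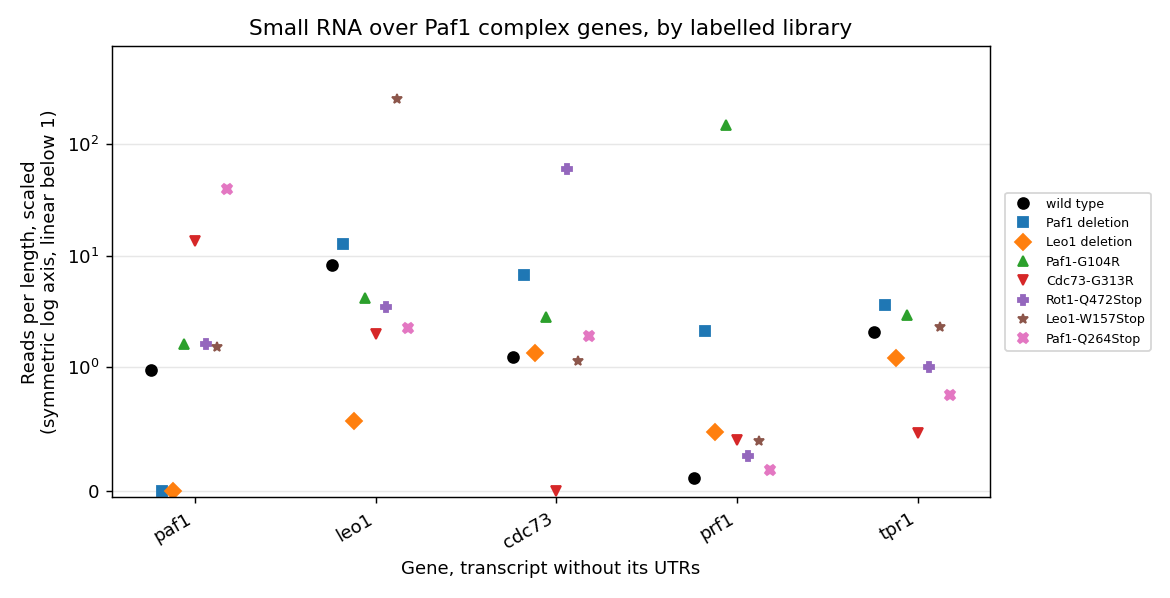
Scaled reads per length (symmetric log axis) over 5 Paf1 complex genes without their UTRs, 1 point per library. The highest point lies at prf1 in the library labelled Paf1-G104R (823 reads), at cdc73 in Rot1-Q472Stop (149 reads), at leo1 in Leo1-W157Stop (519 reads) and at paf1 in Paf1-Q264Stop (181 reads).

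Small RNA around ade6 was higher than in wild type in all 7 mutant libraries. At bub1, which encodes a spindle checkpoint kinase and lies next to ade6 (chromosome 3, 1312560 to 1316005, minus strand), wild type held 110 reads over the transcript. The mutant libraries held between 538 and 99323. The level ratio ran from 18.1 (14.7 to 22.4) in the library labelled Cdc73-G313R to 1933 (1604 to 2352) in that labelled Leo1 deletion, with 66.9 (55.1 to 81.9) in Paf1 deletion. The ade6 5′ UTR (1316243 to 1316336, plus strand) stood at 5.52 in wild type and between 8.42 and 13.65 in the mutants, a median difference of 7.62 on the log2 scale (SD 2.22 over the 7 mutant libraries). At the other neighbour, vtc4 (1318375 to 1321275, minus strand), whose product makes polyphosphate, 6 reads in wild type stood against 30 to 6185 reads in the mutants. Its level ratio ran from 18.5 (7.57 to 54.3) in Cdc73-G313R to 2207 (1013 to 6015) in Leo1 deletion.

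Over the ade6 transcript itself (1316243 to 1318070), which encodes an enzyme of purine synthesis, wild type already held 237288 reads, a level of 14.64. In 5 mutant libraries the level was higher, with ratios of 2.90 (2.88 to 2.91) in Leo1 deletion, 3.90 (3.88 to 3.92) in Paf1-G104R, 2.67 (2.65 to 2.69) in Rot1-Q472Stop, 3.80 (3.78 to 3.82) in Leo1-W157Stop and 3.10 (3.08 to 3.12) in Paf1-Q264Stop. The libraries labelled Paf1 deletion and Cdc73-G313R were lower, at 0.545 (0.538 to 0.551) and 0.208 (0.204 to 0.212). Directions held under the other scalings but sizes did not. Quantile normalization lowered the differences of the 5 higher libraries to 0.88 in Paf1-G104R and 0.39 in each of the others, below the threshold of 1. Recentring moved Cdc73-G313R from -2.26 to -0.26. The ade6 3′ UTR (1317996 to 1318070) differed little in median, by -0.16, and was higher in 3 libraries and lower in 4. The bub1 5′ UTR (1315933 to 1316005) was higher in all 7 mutants, by a median of 7.46, and its 3′ UTR (1312560 to 1312797) by 2.44, although the latter passed 1 in 4 libraries and its interval reached 1 in Paf1 deletion, Cdc73-G313R and Leo1-W157Stop. The vtc4 5′ UTR was higher by a median of 4.29. Its 3′ UTR (1318375 to 1318424) held 0 reads in wild type and 0 to 13 in the mutants. Over all 9 elements of the locus, without the level filter, the median difference ran from 0.59 in Cdc73-G313R, where 6 were higher and 2 lower, to 6.56 in Leo1 deletion.

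**Figure D2:**
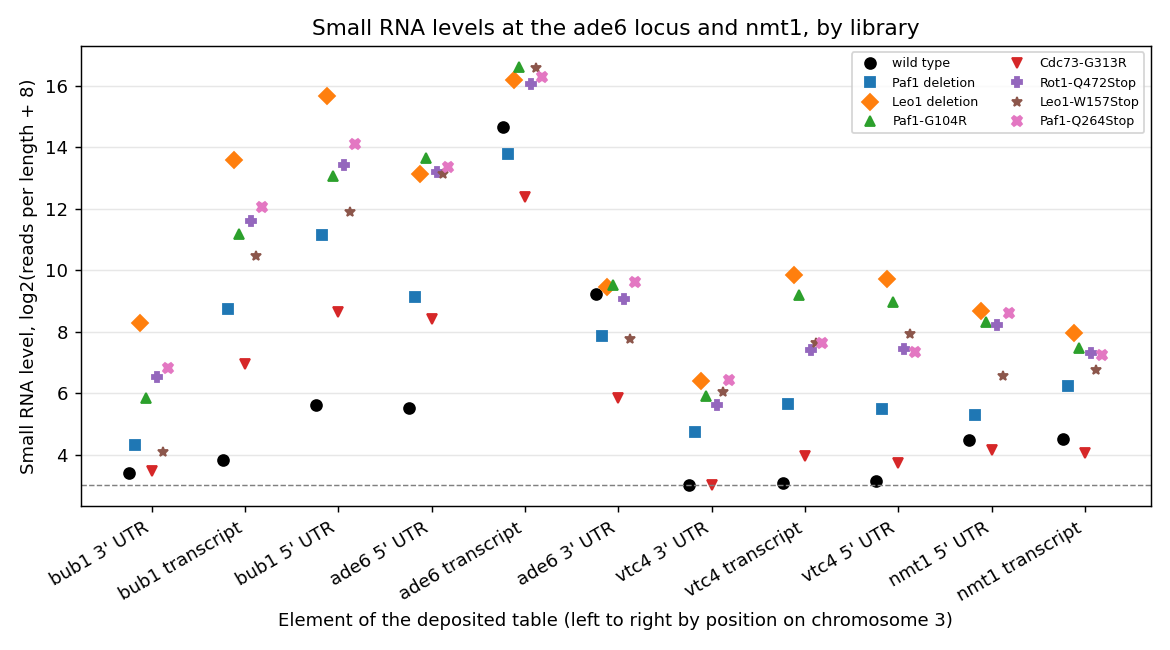
Level on the log2(value + 8) scale at 9 elements of the ade6 locus and 2 of nmt1 on chromosome 3, 1 point per library, with the floor of the table at 3 as a dashed line. At the bub1 transcript wild type lies at 3.84 and the mutant libraries between 6.93 and 13.57, while at the ade6 transcript wild type (14.64) lies within the mutant range of 12.38 to 16.61.

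At nmt1 (chromosome 3, 1838335 to 1839525, plus strand), a thiamine-repressed gene whose promoter is widely used for expression constructs, 6 mutant libraries were higher than wild type. The transcript held 88 reads in wild type. Ratios were 16.3 (13.1 to 20.6) in Leo1 deletion, 11.6 (9.28 to 14.7) in Paf1-G104R, 10.3 (8.14 to 13.2) in Rot1-Q472Stop, 9.76 (7.78 to 12.4) in Paf1-Q264Stop, 6.77 (5.20 to 8.88) in Leo1-W157Stop and 4.61 (3.38 to 6.29) in Paf1 deletion. The library labelled Cdc73-G313R held 14 reads, a ratio of 0.588 (0.309 to 1.04) whose interval includes 1. The nmt1 5′ UTR (1838335 to 1838484) had a median difference of 3.72 and passed 1 in 5 libraries. Its interval included a ratio of 1 in Paf1 deletion (2.17, 0.59 to 6.78) and in Cdc73-G313R (0.67, 0.07 to 3.08).

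Lists of elements were compared with wild type next. They were fixed before the data were examined, except that some planned lists were split, as described under processing. Lists of pericentromeric non-coding RNAs and of telomeric, subtelomeric and pre-rRNA elements were taken from classes of the deposited table. The libraries differed in their general level. The median difference of all elements past the filter was 0.01 in Paf1 deletion, -0.70 in Leo1 deletion, -0.11 in Paf1-G104R, -2.002 in Cdc73-G313R, -0.39 in Rot1-Q472Stop, -0.48 in Leo1-W157Stop and -0.31 in Paf1-Q264Stop. Relative medians below are list medians minus these shifts. A member near the floor in wild type passes the filter only if the mutant is high, so medians over all members, with neither filter nor shift, are given beside them. The setting without the filter was planned, and placing it beside these lists was decided after seeing the data.

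Telomeric small RNA was far lower in every mutant library. The 16 telomeric elements past the filter had a median relative difference of -1.92 in Paf1 deletion, -2.40 in Leo1 deletion, -3.78 in Cdc73-G313R, -4.44 in Paf1-G104R, -4.56 in Paf1-Q264Stop, -4.87 in Leo1-W157Stop and -5.49 in Rot1-Q472Stop, each at percentile 0.00 of random lists. Between 11 and 16 of the 16 were lower by at least 1, and 0 were higher. Over all 27 members, 11 of which lay below the filter, the median difference ran from -0.59 in Paf1 deletion to -2.94 in Cdc73-G313R. SPAC212.10 (chromosome 1, 5726 to 6331) stood at 13.71 in wild type and 4.64 to 8.61 lower in the mutants, and SPBCPT2R1.10 (chromosome 2, 4526225 to 4526884) differed by -4.62 to -8.57. The telomere-linked helicase genes tlh1 (chromosome 1, 1 to 5662) and tlh2 (chromosome 2, 4526885 to 4532899) had median differences of -4.87 and -4.86. These copies share reads and are not independent. Random lists draw members separately, so the percentiles of this list are descriptive only. Of the 21 SPAC212 and SPBCPT2R1 genes, 7 passed the filter, with relative medians between -2.62 and -7.11, while the median over all 21 lay between -0.13 and 0.05. Of 113 subtelomeric elements at most 6 passed in any comparison. Of these, 0 reached the filter in wild type, so only raised members could enter and no direction is given for this list. The mat3 genes mat3-Mi and mat3-Mc stayed near the floor, at 3.17 and 3.14 in wild type, and did not pass.

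Pericentromeric small RNA was lower by a smaller amount, and under quantile normalization the median difference of its repeats ran from -2.05 to 0.04, above 0 in Paf1 deletion. Relative medians of the 53 pericentromeric repeats, of which 48 or 49 passed, were -0.34 in Leo1 deletion, -0.36 in Paf1 deletion, -0.63 in Paf1-Q264Stop, -0.89 in Paf1-G104R, -1.28 in Leo1-W157Stop, -1.57 in Rot1-Q472Stop and -2.03 in Cdc73-G313R. All but Paf1 deletion (percentile 6.77) lay at or below percentile 0.02. Over all 53 members the median difference ran from -0.33 in Paf1 deletion to -4.03 in Cdc73-G313R. The 14 pericentromeric non-coding RNAs past the filter had relative medians between -0.40 and -2.29. Among them SPNCRNA.371 (chromosome 2, 1636393 to 1636776) had a median difference of -1.68, SPNCRNA.232 (chromosome 1, 3762865 to 3763969) of -1.51 and SPNCRNA.234 (chromosome 1, 3786105 to 3787136) of -1.31, each lower in 7 of 7 libraries. In Paf1 deletion the relative median of the 14 was -0.46, at percentile 19.41, and 13 of them differed by less than 1. Over all 26 members the median difference ran from -0.01 in Paf1 deletion to -2.62 in Cdc73-G313R. Of the repeats of highest level, unknown_78 (chromosome 2, 1638230 to 1644747) differed by a median of -0.79, unknown_77 (chromosome 3, 1091700 to 1097063) by -0.64, unknown_148 (chromosome 1, 3763442 to 3769077) by -0.70 and unknown_97 (chromosome 3, 1135372 to 1137003) by -1.31. The first 3 were each higher in 1 library. These differences are not corrected for the general shift of a library, which was -2.002 in Cdc73-G313R. There unknown_78 (-0.99), unknown_77 (-0.67) and unknown_148 (-0.14) fell by less than the shift, so relative to it they were higher than wild type. Only unknown_97 (-4.70) fell by more. Relative to the shift unknown_77 was also higher in Rot1-Q472Stop (0.055, shift -0.39) and Leo1-W157Stop (-0.30, shift -0.48). Relative medians of LTR elements, with 7 to 13 of 221 past the filter, ran from -0.70 to 0.26, and medians over all 221 from -0.32 to 0.00. A single Tf2 element of 27 passed, with a median difference of 0.44, and 0 of 28 wtf genes did. Medians over all 27 Tf2 elements ran from -0.14 to 0.09.

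**Figure D3:**
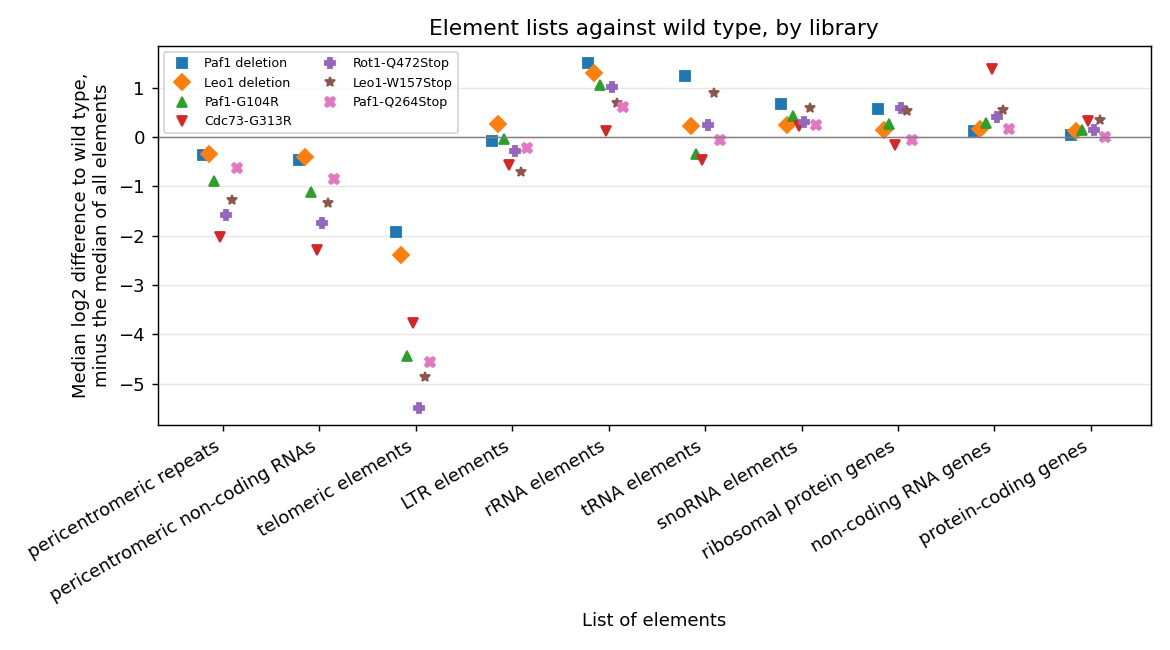
Median log2 difference to wild type of 10 lists of elements, minus the median of all elements past the filter, over members past it in either library, 1 point per mutant library. Telomeric elements lie between -1.92 and -5.49 and pericentromeric repeats between -0.34 and -2.03 (up to 0.04 under quantile normalization), while protein-coding genes lie between 0.01 and 0.34.

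Structural RNA took very different shares of the linear total. That total sums reads per length, so a short element weighs more in it than in reads. The rRNA class held 4.28% of the linear total in wild type, 28.7% in Paf1 deletion, 12.8% in Leo1 deletion, 8.54% in Paf1-G104R, 60.02% in Cdc73-G313R, 22.3% in Rot1-Q472Stop, 26.1% in Leo1-W157Stop and 8.84% in Paf1-Q264Stop. It was thus higher in all 7 mutants, beside the lower telomeric and pericentromeric levels. Nearly all of it lay at 1 element of 98 nt, unknown_53 (chromosome 3, 814799 to 814896), whose plus strand matches the large rRNA gene with 98.9% identity over 88 nt in the reference. Its level was 15.22 in wild type, 16.22 to 19.05 in the mutants. The 7 transcript, UTR or non-coding RNA elements lying opposite a tRNA gene, where its fragments are counted, took 2.19% of recovered reads in wild type, 8.57% in Cdc73-G313R, 4.11% in Paf1 deletion and 1.63% to 2.65% in the others. The 23 such elements opposite snoRNA genes took 0.189% in wild type and 0.232% to 0.834% in the mutants. The 3 opposite rRNA genes took 6.34% of recovered reads in wild type, 30.7% in Cdc73-G313R and 8.71% to 17.3% in the other mutants. By the same strand check the annotated elements of structural RNA genes are read as mostly antisense to the RNA, which was not tested for each gene. Over all members their medians ran from -1.43 in Cdc73-G313R to 1.05 in Paf1 deletion for tRNA, from -0.25 to 1.03 for rRNA, from -1.86 to 1.39 for pre-rRNA, from -0.998 to 1.77 for snRNA and from -0.42 to 0.62 for snoRNA. Of the 4 snoRNA elements of highest level, snR5 was higher in 6 libraries and lower in 1 (median difference 1.19), snR10 higher in 7 (1.19), snR40 lower in 7 (-0.73) and snR46 higher in 2 and lower in 5 (-0.52). In Leo1 deletion the difference at snR40, -0.24, was smaller than the general shift of that library. On the strand reading above these values do not measure the snoRNAs themselves, which was not tested for these 4 elements. No mitochondrial element was in the table analysed here.

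Gene lists without heterochromatic members differed in how far they moved. Protein-coding genes had relative medians between 0.01 and 0.34, and ribosomal protein genes between -0.17 and 0.58. Non-coding RNA genes lay between 0.13 in Paf1 deletion and 1.38 in Cdc73-G313R. Over all members the medians lay between -0.29 and 0.15, -0.15 and 0.47, and -0.21 and 0.05, in this order. Of the housekeeping genes, adh1 (alcohol dehydrogenase, chromosome 3, 1589427 to 1592889) passed in every comparison, with a median difference of 0.92. It was higher in 6 libraries and lower by -1.59 in Cdc73-G313R, a difference smaller than the general shift of that library, -2.002. Over all 7 housekeeping genes the median ran from -0.19 in Cdc73-G313R to 1.65 in Paf1 deletion, where 7 of 7 were higher. In that library pgk1 differed by 2.35 and eno101 by 2.26, both below the filter in wild type. No member of the RNAi and heterochromatin list or the meiotic list reached the filter. The highest were stc1 (median difference -0.29), rdp1 (-0.12), mei4 (0.63) and crs1 (-0.57).

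Each mutant library was then compared with wild type over single elements, counting differences of at least 1 on the log2 scale. Most mutants had more lower than higher elements, and this balance depended on centring. The counts of higher and lower elements were 654 and 582 in Paf1 deletion, 113 and 659 in Leo1 deletion, 111 and 237 in Paf1-G104R, 85 and 1624 in Cdc73-G313R, 202 and 634 in Rot1-Q472Stop, 213 and 804 in Leo1-W157Stop, and 87 and 289 in Paf1-Q264Stop. After recentring they were 650 and 584, 217 and 138, 141 and 184, 546 and 371, 332 and 375, 437 and 500, and 146 and 161, in the same order. After rescaling by the median ratio, a choice made after seeing the data, they were 335 and 887, 238 and 284, 102 and 265, 97 and 1599, 191 and 647, 169 and 882, and 120 and 224, so that the balance in Paf1 deletion turned to lower elements. This ratio was taken only over elements with at least 30 reads and did not centre every library. It was 0.934 in Cdc73-G313R and 1.39 in Paf1 deletion, where the median differences of all elements past the filter were -2.002 and 0.01. Whether the turn in Paf1 deletion comes from this choice of elements was not tested. Counting noise alone gave means between 48.5 and 161 changed elements per library in 100 simulations.

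Among protein-coding and non-coding genes, bub1 had the largest positive difference in every library except that labelled Cdc73-G313R. Next in Paf1 deletion came pil1 (4.24), an eisosome gene, and usp108 (3.19), and next in Leo1 deletion ptc2 (7.96), a phosphatase gene on chromosome 3 (1863661 to 1866637), and vtc4 (6.75). In Paf1-G104R vtc4 (6.12) and SPNCRNA.1233 (5.31) followed. In Rot1-Q472Stop and Paf1-Q264Stop, SPNCRNA.10 (4.59 and 4.43), which lies beside nmt1, and vtc4 (4.32 and 4.56) followed. In Leo1-W157Stop SPNCRNA.1233 (6.23) and spp27 (5.95) did. The library labelled Cdc73-G313R had SPNCRNA.475 (4.72), arc5 (3.82) and SPNCRNA.87 (3.76). The telomeric gene SPAC750.08c, tlh1 and tlh2 made up the 3 lowest in Paf1-G104R, Rot1-Q472Stop, Leo1-W157Stop and Paf1-Q264Stop. Others among the lowest were SPNCRNA.276 (-3.84) and mae2, the malic enzyme gene (-3.81), in Paf1 deletion, and mae1, a malate transporter gene, in Leo1 deletion (-3.59) and Cdc73-G313R (-5.75).

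Of 3402 elements past the filter in at least 1 library, 9 were higher and 48 lower by at least 1 in all 7 mutants. The 9 were the bub1 transcript and 5′ UTR, the ade6 5′ UTR, the hel2 5′ UTR (6.13), SPNCRNA.1233 (4.09), the spp27 transcript (4.08), the SPBC1685.12c 5′ UTR (1.85), the mug114 5′ UTR (1.63) and SPNCRNA.1374 (1.31), with median differences in parentheses. The spp27 gene (chromosome 3, 1831913 to 1834169) and hel2 lie within 7 kb of nmt1, and SPNCRNA.1233 overlaps spp27. In 3 of the 9 wild type held 0 reads. The hel2 UTR, 14 nt long, held 1 to 34 mutant reads, the SPBC1685.12c UTR 2 to 6 and the mug114 UTR 1 to 9, and their intervals reached a ratio of 1 in 2, 3 and 4 libraries. Of the 48 lower elements 10 were telomeric, 20 were 3′ UTRs and 3 had 0 reads in every mutant and 1 or 2 in wild type. For 10 of the 48 the interval of the ratio reached 1 in at least 1 library. The 10 with the largest median differences were unknown_1 (-6.31), SPBCPT2R1.10 (-6.28), SPAC212.10 (-6.28), SPAC212.09c (-6.25), SPBCPT2R1.07c (-6.23), unknown_2 (-5.48), the mae1 5′ UTR (-5.35), SPAC750.08c (-5.22), tlh1 and tlh2. Simulations with no difference except depth gave a mean of 0.370 higher and 1.1 lower elements, with maxima of 2 and 5, and independent lists of these sizes would share 0.0316 lower elements and fewer higher ones. Part of any excess can come from the shared wild-type library. Some of these elements also hold the same reads, such as tlh1 and tlh2, or the bub1, mae1 and alg12 transcripts and their own UTRs. The counts are therefore of elements and not of separate loci. The simulations drew each element separately, so their maxima do not allow for shared reads. With each mutant library as the reference the counts of elements higher and lower in all others ran from 1 and 9 (Paf1-Q264Stop) to 777 and 16 (Cdc73-G313R) and 9 and 330 (Paf1 deletion). Without the libraries labelled Paf1 deletion and Cdc73-G313R, a choice made after seeing the data, the counts were 30 and 90.

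Alleles of the same gene were compared last. The libraries labelled Paf1-G104R and Paf1-Q264Stop were the closest pair of all 28, with 242 of 2229 elements differing by at least 1 and a Pearson correlation across elements of 0.92. The first of these labels is in conflict with the small RNA over prf1. These were also the mutant libraries with the most reads (3139592 and 3156301) and the fewest elements differing from wild type (348 and 376). The libraries with raised paf1, labelled Cdc73-G313R and Paf1-Q264Stop, differed at 1352 of 1805 elements (74.9%), with a correlation of 0.68. The library labelled Cdc73-G313R differed from every other library at 67.3% to 78.8% of elements, so this value says little about paf1 alleles. Which libraries are paf1 alleles depends on the labels, and their likeness stays open. The Paf1 deletion library differed from that labelled Paf1-G104R at 1115 of 2859 elements, with a correlation of 0.68, and from that labelled Paf1-Q264Stop at 1142 of 2722, with a correlation of 0.70. The Leo1 deletion library and that labelled Leo1-W157Stop differed at 503 of 1875 elements, with a correlation of 0.83. Over the 17 pairs of mutants labelled with different genes, the correlation ran from 0.67 to 0.90 and the number of differing elements from 302 to 1750. Elements are not independent replicates, and these values describe the libraries. Between the alleles of Leo1, the bub1 transcript stood at 1933 times the wild-type level in the deletion and 221 times in Leo1-W157Stop.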

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

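These values were picked out because the counting intervals of 2 alleles of the same gene lay on opposite sides of the wild-type level, a rule set after the data were seen, in place of an earlier one with a minimum size of difference. With 1 library per allele the differences were not tested. At the ade6 transcript the library labelled Paf1 deletion was lower than wild type (ratio 0.545, 0.538 to 0.551), while those labelled Paf1-G104R (3.90) and Paf1-Q264Stop (3.10) were higher. The difference of Paf1 deletion minus Paf1-G104R was -2.84 on the log2 scale, and that of Paf1 deletion minus Paf1-Q264Stop was -2.51. At the ade6 3′ UTR, Paf1 deletion stood at a ratio of 0.382 (0.222 to 0.618) and Paf1-Q264Stop at 1.30 (1.07 to 1.58), a difference of -1.73. The library labelled Paf1-G104R carries the label conflict described for the Paf1 complex genes. The libraries also differed in composition. The rRNA class held 28.7% of the linear total in Paf1 deletion, 8.54% in Paf1-G104R and 8.84% in Paf1-Q264Stop. Introns held 1.61%, 22.3% and 25.9%, in this order. In Cdc73-G313R, where the ade6 transcript was also lower, these shares were 60.02% and 2.22%. A difference in library composition therefore cannot be told apart from one between alleles.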

How the results depend on the processing

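The alternatives that rescale by the median ratio or leave out several libraries at once were chosen after seeing the data, and so was the counting interval against which medians are judged. Counts are given in the order Paf1 deletion, Leo1 deletion, Paf1-G104R, Cdc73-G313R, Rot1-Q472Stop, Leo1-W157Stop and Paf1-Q264Stop. The total of changed elements was 1236, 772, 348, 1709, 836, 1017 and 376. Without a level filter it was 2283, 1191, 591, 3199, 1356, 1690 and 611, and with a filter of 4 above the floor (in place of 2) it was 300, 218, 114, 393, 247, 277 and 121, because more or fewer elements entered. A pseudocount of 4 gave 2347, 1351, 660, 3052, 1439, 1750 and 724. A 1.5-fold threshold gave 1892, 1445, 856, 1360, 1548 and 898 without Cdc73-G313R, whose count stayed within 1.5 times. A 4-fold threshold gave 419, 144, 93, 1116, 220, 340 and 88. Recentring moved Leo1 deletion to 355 and Cdc73-G313R to 917, and quantile normalization moved Leo1 deletion to 406. Rescaling by the median ratio left 27.4% of changed elements higher in Paf1 deletion, against 52.9%. Under quantile normalization 34.8% of changed elements in Cdc73-G313R and 43.4% in Leo1 deletion were higher, against 4.97% and 14.6% as deposited. The cause was not tested.

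Of the elements changed in all 7 mutants, 9 higher and 48 lower, recentring gave 37 and 24, of which 9 and 24 were the same elements. Quantile normalization gave 23 higher, a filter of 4 gave 26 lower, and a pseudocount of 4 gave 84 lower. Thresholds of 1.5-fold and 4-fold gave 21 and 228, and 4 and 14. Leaving out 1 library gave 9 to 21 higher and 48 to 91 lower, with 21 higher without Cdc73-G313R, and 89, 91 and 73 lower without Paf1 deletion, Paf1-G104R and Paf1-Q264Stop. With another library as the reference, 330 were lower for Paf1 deletion, 3 higher for Leo1 deletion, 2 and 9 for Paf1-G104R, 777 and 16 for Cdc73-G313R, 2 and 19 for Rot1-Q472Stop, 22 lower for Leo1-W157Stop and 1 and 9 for Paf1-Q264Stop. Without Paf1 deletion and Cdc73-G313R there were 30 and 90, with recentring in addition 58 higher, and without the 3 libraries at odds with their labels 27 and 101.

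The median over mutants of a list or an element is set here against its 95% counting interval, from 200 draws of the reads, which covers no variation between strains. Of 130 alternatives for lists 56 stayed within it, and of 76 for the ade6 locus and nmt1 58 did. No direction is read from the subtelomeric medians below. As deposited, 0 members of that list reached the filter in wild type, so only raised members entered. Without the filter the median of that list was 0.00. Recentring gave -0.89 for pericentromeric repeats, -1.12 for pericentromeric non-coding RNAs, -4.44 for telomeric and 2.42 for subtelomeric elements, -5.64 for SPAC212 and SPBCPT2R1 genes, 0.82 for Tf2, -0.22 for LTR, 1.006 for rRNA, 1.22 for pre-rRNA, 0.23 for tRNA, 1.21 for snRNA and 0.30 for snoRNA. It gave 1.73 for housekeeping, 0.29 for non-coding RNA and 0.14 for protein-coding genes, 1.94 for the ade6 transcript, 0.23 for its 3′ UTR, 4.87 and 4.68 for the vtc4 transcript and 5′ UTR, and 3.04 for the nmt1 transcript. Quantile normalization gave -0.23 for pericentromeric repeats (-1.05 as deposited), -0.52 for pericentromeric non-coding RNAs (-1.23), -3.81 for telomeric (-4.87) and 2.04 for subtelomeric elements (1.85), -5.43 for SPAC212 and SPBCPT2R1 genes (-6.21) and 0.39 for the ade6 transcript (1.53). It gave 0.68 for Tf2, 0.85 for rRNA, 1.13 for pre-rRNA, 0.0742 for tRNA, 1.02 for snRNA, 0.26 for snoRNA, 1.77 for housekeeping, 0.25 for non-coding RNA and 0.0274 for protein-coding genes.

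Without a level filter members near the floor entered, which gave -1.02 for pericentromeric repeats, -1.06 for pericentromeric non-coding RNAs, -1.51 for telomeric and 0.00 for subtelomeric elements, -0.0595 for SPAC212 and SPBCPT2R1 genes and 0.0668 for Tf2. It gave -0.0754 for LTR, 0.0649 for rRNA, 0.20 for snRNA, 0.14 for housekeeping and -0.0613 for protein-coding genes. A filter of 4 gave -5.04 for telomeric elements, 2.86 for Tf2, 2.61 for rRNA, 0.72 for pre-rRNA, -1.35 for tRNA, 2.34 for snRNA, 0.92 for housekeeping, 0.20 for non-coding RNA and 0.0934 for protein-coding genes. A pseudocount of 4 gave -3.77 for telomeric and 0.33 for subtelomeric elements, -0.80 for LTR, 0.99 for pre-rRNA, -0.16 for tRNA, -0.48 for snoRNA, 1.23 for housekeeping, -0.36 for ribosomal protein and -0.29 for protein-coding genes. It gave 3.02 and 7.81 for the bub1 3′ UTR and transcript, and 3.80, 5.44 and 5.12 for the vtc4 3′ UTR, transcript and 5′ UTR. Means over members gave -1.02 for pericentromeric repeats, -3.79 for telomeric elements, -5.21 for SPAC212 and SPBCPT2R1 genes, 0.82 for rRNA, 0.39 for pre-rRNA and -0.17 for protein-coding genes. Without members that share reads, housekeeping genes stood at 2.26, ribosomal protein genes at -0.38, non-coding RNA genes at -0.17 and protein-coding genes at -0.46. Rescaling by the median ratio gave -1.28 for pericentromeric non-coding RNAs, -4.70 for telomeric elements, 0.46 for rRNA, 0.78 for pre-rRNA, 1.23 for housekeeping and -0.0232 for non-coding RNA genes, 1.795 for the ade6 transcript and 4.42 for the vtc4 transcript. Without Paf1 deletion and Cdc73-G313R the bub1 3′ UTR stood at 3.12, its transcript at 7.77, the ade6 transcript at 1.63, its 3′ UTR at 0.22 and the vtc4 5′ UTR at 4.76. Signs changed in 14 cases over 5 lists with medians between -0.37 and 0.05 (tRNA, snoRNA, ribosomal protein, non-coding RNA and protein-coding genes), and in 3 for the ade6 3′ UTR. The sum of both strands and each strand alone at ade6 were not run, since the table holds 1 value per element.

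Between alleles, in the order Paf1 deletion against Paf1-G104R, Paf1 deletion against Paf1-Q264Stop, Leo1 deletion against Leo1-W157Stop and Paf1-G104R against Paf1-Q264Stop, differing elements numbered 2207, 2185, 1047 and 501 without a filter and 260, 239, 137 and 51 with a filter of 4. A pseudocount of 4 gave 2220, 2254, 1046 and 538. The 1.5-fold threshold gave 1749, 1734, 1058 and 667, and the 4-fold threshold 397, 359, 123 and 47. In the library labelled Cdc73-G313R 43.8% of elements held any read, against 75.6% in wild type, while counting noise alone changed the most elements in Paf1 deletion, 161 in the mean.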

Other observations

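All tests in this part were chosen after the results they bear on had been seen, and so were the loci beside cox4 and nmt1. Relative to element length, small RNA was most abundant in wild type at the sequence of the cox4 intron (chromosome 1, 711413 to 711767). The labels used here do not say whether the strains carry an expressed construct with this intron or with parts of ade6 or nmt1, so the source of reads at these 3 places stays open. It stood at 17.05 in wild type, 17.20 to 17.82 in 4 mutant libraries, 16.78 in Leo1-W157Stop, 14.24 in Cdc73-G313R and 13.35 in Paf1 deletion. The cox4 5′ UTR held 6 reads in wild type and was higher in 7 of 7 mutant libraries, by a median of 4.64, although the counting intervals of Paf1 deletion (3 reads) and Cdc73-G313R (6 reads) included a ratio of 1. Beside nmt1, the non-coding RNA SPNCRNA.10 was higher in 7 of 7 by a median of 4.43, while SPNCRNA.1234, which spans it on the same strand, was lower in 7 of 7, by a median of -1.07. In Leo1 deletion the latter difference, -0.56, was smaller than the general shift of that library, -0.70.

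The gain of small RNA around ade6 was examined at the transcripts of both neighbours, bub1 and vtc4, in place of earlier tests on a chosen part of the locus. The lowest bound of the counting interval over both transcripts and 7 libraries was a ratio of 7.57, which argues against counting error in shallow libraries, and 8.1095 after division by the median ratio of the library, which argues against library scaling as its whole cause. Both bounds came from vtc4 in Cdc73-G313R, where the median log2 difference over all 6 bub1 and vtc4 elements was 0.78 after rescaling, so the gain there is small on the deposited scale. Only 1 wild-type library was sequenced, so a chance value of that library cannot be told apart from an effect of the mutations. An effect of losing Paf1 complex function on spreading of small RNA into neighbouring genes may be a biological explanation, and neither it nor a construct was tested.

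In all 3 libraries at odds with their label, the raised gene was the labelled gene of another of these 3, if Rot1 is read as prf1, which is what an exchange of the labels Paf1-G104R, Cdc73-G313R and Rot1-Q472Stop among each other would give. The lowest counting bound over the 5 libraries was a ratio of 5.81, which argues against counting error. At most 0.749% of 18 nt windows in a raised gene had a second exact site in the reference, which argues against reads shared with other sites, and replaced a test of whether read numbers were whole that had left this open. An exchange of labels may be a candidate explanation, but the library labelled Paf1 deletion also had cdc73 and prf1 above wild type, at 9 and 4 reads. Why a mutated gene would carry small RNA was not tested, and the comparisons by label were left as given.

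The loss of telomeric small RNA was seen in all 7 mutant libraries, where the highest per-library median difference over the 16 elements past the filter in wild type was -2.39 after rescaling, which argues against library scaling. With the rRNA class taken out of each total it was -1.50, which argues against dilution by the fragments counted in that class. Fragments counted at other elements opposite structural RNA genes stayed in the total, so dilution by these was not tested. RNA quality as such stays open. The telomeric minus the pericentromeric median was -1.56 at the highest, in Paf1 deletion, which argues against an equal loss of all heterochromatic small RNA. A chance value of the 1 wild-type library cannot be told apart from an effect of the mutations. A loss through the Paf1 complex mutations may be a biological explanation and stays untested, as does a telomere variant between strains.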
